A study of Mus musculus with 10 samples.

How the data were processed

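Poly(A)-selected RNA from the visceral fat of 10 male mice was sequenced, 1 library per mouse, 5 labelled WT and 5 labelled aADM2-tg. The deposited table holds, for 56691 genes, read counts of the 10 libraries, exonic gene lengths and, for 7 libraries, FPKM. Its count columns are raw read counts per gene per the file headers, 1 column per mouse. Its FPKM columns were made by the authors as counts per kilobase of exonic length and per 1e6 reads counted to genes. Recomputing FPKM from the counts matched the deposited values within 0.01 for 56691 genes in 6 of the 7 libraries and for 56661 in WT3, and 3 further FPKM columns, whose names match the labels of more than 1 sample, were not used. The submitters' processing notes name HISAT2 2.2.1 and HTSeq 0.6.1. The genome build, the annotation release and the strand setting are not given in the sources used here. Of 52073 gene identifiers shared with GENCODE M21, 1435 had the same coordinates as on GRCm38, so coordinates are printed as the file gives them with no build. In the file 2639 genes carry no symbol and 77 symbols stand on more than 1 entry.

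The group of each library was taken from the sample labels, which the second header line of the file follows. The first header line names the columns in the opposite sense. The titles and descriptions of the transgenic samples 3, 4 and 5 disagree on their number, and 2 of these columns share an identifier, so tg3, tg4 and tg5 are named after the numbers in the column names. This changes neither the group of a library nor its counts, but the replicate block and the comparison of libraries by number rest on these numbers.

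Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries were scaled by TMM, and aADM2-tg was compared with WT by quasi-likelihood tests with genotype as the only term, over all 10 libraries. P values were adjusted by the Benjamini-Hochberg method over the 16591 tested genes, with a threshold of 0.05. Printed CPM are counts per 1e6 of all counted reads. Log2 CPM for principal components and correlations used a prior count of 2. Adm2, which did not pass the expression filter, was compared by an exact two-sided permutation test of the mean log2 of CPM plus 1. The floor of 3 counts covers counting error only, and sequencing reads without molecular identifiers are not independent molecules.

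Gene lists were fixed, with the tests, the alternatives and the rule for named genes, before the data were examined: 47 lists with 796 entries, of which 795 matched the file, 3 of them through an older symbol. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The named genes are the adrenomedullin system, the 10 largest rises and the 10 deepest falls among called genes whose groups do not overlap and whose mean reaches 1 FPKM in the higher group, without predicted genes or antigen receptor segments, and up to 4 called genes of each list by adjusted p, or values of 2 members where a list had none. Pcna and Gadd45b were named in addition, after their values were seen. Some genes that the rule names are not reported here. Lists that share genes were tested separately.

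The alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma-trend on log2 of FPKM plus 1 (genes with at least 1 FPKM in 5 libraries, FPKM computed from the counts), voom with sample quality weights, no expression filter, a filter at a mean of 10 CPM, each library left out in turn, and the replicate number as a block. Chosen after seeing the data were a duct score (the mean log2 CPM of 27 duct and ciliated epithelium genes) as a term beside genotype, a correction of each library for its trend with exonic length and GC content (loess, span 0.3), both together, leaving out WT1 and tg2, leaving out the 5 libraries with duct RNA, and camera over gene ontology terms with 10 to 300 tested members. A GC value was at hand for 98.5% of tested genes. For other splits of the libraries, 100 of the 126 possible splits into 5 and 5 were drawn with a fixed seed. Within each group of 5, a library was listed as far from the others when its gap to the nearest one, over the range of the group, passed Dixon's 95% critical value.

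The method was tested on simulated data with 2 groups of 5 libraries. Of 95 genes changed 2-fold 63.2% were called and of 100 genes changed 4-fold 90% were called, 7 of 171 calls were false, and with no gene changed there were 0 calls among 16242 tested. Calls of genes planted with a smaller change were not counted as false. The simulated genes varied independently, with no RNA shared by some libraries, so this does not give the rate of false calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.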

Results

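RNA was sequenced from the visceral fat of 10 male mice, 10 weeks old and kept on chow for 8 weeks. The libraries fall into 2 labelled groups of 5: WT (WT1 to WT5) and aADM2-tg (tg1 to tg5), described as mice that overexpress adrenomedullin 2 in fat. The comparison asks how the transcripts of visceral fat differ between the labelled groups. The overexpression itself could not be seen in the counts, as given below. Counted reads numbered 18064306 in WT1, 17777118 in WT2, 16921357 in WT3, 17718171 in WT4 and 17803323 in WT5. In the transgenic group they numbered 16660415 in tg1, 16402654 in tg2, 16030435 in tg3, 18214504 in tg4 and 16783874 in tg5. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to 0.165 to 0.187 counts per 1e6 counted reads (CPM). Each ± below is the SD of CPM over n = 5 libraries, and each log2 value is the fitted change of aADM2-tg over WT.

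In the libraries labelled aADM2-tg, 19 of 27 extracellular matrix genes and 17 of 26 cell cycle genes were lower and 1 of each list was higher. The fibrillar collagen gene Col3a1 fell from 3176 ± 962 to 881 ± 127 CPM (n = 5), and the proliferation marker Mki67 from 37.0 ± 15 to 10.96 ± 2.44 CPM (n = 5). Of 18 genes of lipolysis and the lipid droplet 11 were higher and 0 lower, among them the fat-cell adrenergic receptor Adrb3, from 501 ± 119 to 994 ± 134 CPM (n = 5). Of 11 heat shock genes 10 were higher and 0 lower, and the small heat shock protein gene Hspb1 was 3.94-fold higher, at 123 ± 50.3 against 32.7 ± 6.65 CPM (n = 5). As whole lists these 4 were called by camera at a preset correlation between genes, and none was with an estimated correlation (adjusted p = 0.727). RNA of duct and ciliated epithelium, which was high in 4 of the 5 WT libraries and in tg2, moved with the same grouping, and the counts of each gene group with this RNA as a term of the model are given below.

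These directions rest on the sample labels. The file carries 2 header lines that name the columns in opposite ways: the second matches the sample labels, while the first puts names beginning with ADM over the columns labelled WT and names beginning with Veh or con over those labelled aADM2-tg. Adm2 itself (ENSMUSG00000054136, chromosome 15, 89206923 to 89208934, plus strand, build not given in the sources used here) could not settle it. Adm2 had 2 counts in WT3 and 0 in each of the other 9 libraries, at or under the limit of 3 counts, so no difference was detectable at this depth (exact two-sided permutation test, p = 1). The sequence of the transgene is not given in the sources used here, so it is not known whether its reads were counted under this gene.

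Of the receptor parts through which adrenomedullin peptides signal, Ramp2 rose in aADM2-tg. Ramp2 (ENSMUSG00000001240, chromosome 11, 101136854 to 101150372), which pairs with the receptor Calcrl, went from 43.4 ± 3.89 to 67.3 ± 14.7 CPM (log2 0.70, SE 0.147, adjusted p = 0.00784), higher in 5 of 5 transgenic libraries than in any WT library. Its call ended when duct RNA and a correction for gene length and GC content were both in the model (log2 0.43, adjusted p = 0.0812). Calcrl was at 36.0 ± 8.78 and 35.3 ± 8.50 CPM (adjusted p = 0.894) and the related peptide gene Adm at 10.3 ± 0.905 and 12.2 ± 2.97 CPM (adjusted p = 0.152). Ramp1 was at 4.01 ± 1.67 and 2.70 ± 1.86 CPM (adjusted p = 0.409) and Ramp3 at 2.15 ± 1.29 and 1.30 ± 2.15 CPM (adjusted p = 0.619). Calca, which encodes calcitonin and calcitonin gene-related peptide, rose from 0.883 ± 0.211 to 1.79 ± 0.621 CPM (log2 1.07, adjusted p = 0.0204). The call of Calca ended without WT4 (adjusted p = 0.0501) and with the measured duct RNA as a term of the model (adjusted p = 0.127). Of the 7 tested members of the adrenomedullin and CGRP list, 2 were higher, 0 lower and 5 not past the test, with the same 2 when adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.429). With duct RNA in that model, 1 of the list was higher and 0 lower.

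The libraries did not separate by label alone. The first principal component of log2 CPM held 67.2% of the variance and placed WT1 (-39.3) with tg1, tg3, tg4 and tg5 (-71.6 to -57.7), and tg2 (62.0) with the other 4 WT libraries (43.4 to 72.6). Across genes, the library closest to WT1 was tg1 (Spearman 0.980) and the one closest to tg2 was WT4 (0.984). A list of 27 duct and ciliated epithelium genes, chosen after this component was seen, summed to 338.1 to 1007 CPM in WT2, WT3, WT4, WT5 and tg2 and to 74.6 to 92.1 CPM in the other 5 libraries. Esr1 alone made up most of the sum in those other 5, at 64.3 to 81.7 CPM, against 74.8 to 152 CPM in WT2 to WT5 and tg2. Foxj1, the regulator of motile cilia, was at 10.9 to 57.3 CPM in WT2 to WT5 and tg2 and at 0 to 0.110 CPM elsewhere, and Pax8, a transcription factor of duct epithelium, at 5.79 to 20.6 against 0 to 0.536 CPM. Male germ cell genes summed to 194 to 229 CPM in WT2, WT3 and WT5 and to 12.9 CPM in each of WT4 and tg2, against 0.250 to 2.21 CPM elsewhere. None of the 27 duct genes was itself called lower in aADM2-tg. The mean log2 CPM of the 27 genes, called the duct score here, was used as an added term beside genotype. It was -1.84 to -1.19 in WT1, tg1, tg3, tg4 and tg5 and 2.98 to 4.54 in WT2 to WT5 and tg2. With this score in the model, the genotype term rests mainly on WT1 and tg2, the libraries that part from their group on it.

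**Figure D1:**
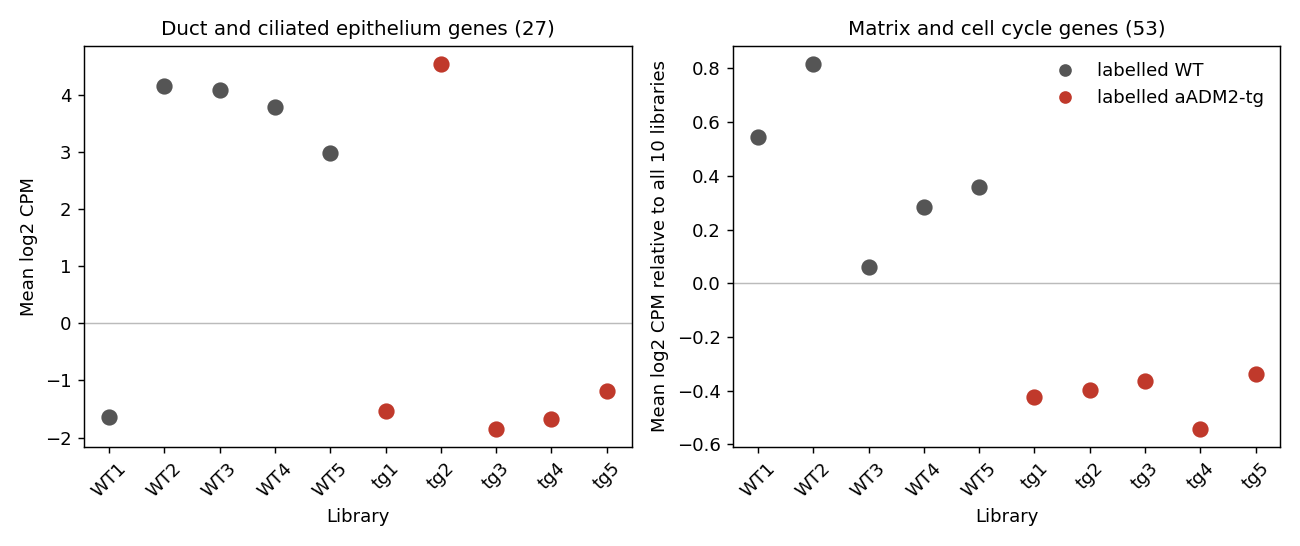
Mean log2 CPM of 27 duct and ciliated epithelium genes (left) and of 53 extracellular matrix and cell cycle genes relative to all 10 libraries (right), 1 point per library, by group. On the left tg2 (4.54) sits with WT2 to WT5 (2.98 to 4.16) and WT1 (-1.64) with the other transgenic libraries (-1.84 to -1.19), while on the right all 5 WT libraries (0.06 to 0.82) lie above all 5 aADM2-tg libraries (-0.54 to -0.34).

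Of 16591 genes tested with edgeR, 2285 were higher and 2107 lower in aADM2-tg at an adjusted p under 0.05, and 221 and 488 of these changed at least 2-fold. In 2762 of the called genes the values of the groups did not overlap. This held for 17.7% of all tested genes, where chance gives 0.794%. With the duct score in the model 822 genes were higher and 1310 lower, of which 725 and 1240 were the same genes as before. Leaving out the 5 libraries with duct RNA, which leaves 1 WT library against 4, gave 1 gene higher and 34 lower, and the lone WT library was assumed to vary like the others. The count of higher genes was 1370 without WT2, 1505 without WT3, 1518 without WT4 and 1515 without WT5. The count of lower genes was 3629 without tg2, the only transgenic library with a high duct score.

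Among the largest rises of genes whose groups did not overlap was that of Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, from 1.28 ± 0.713 to 8.52 ± 4.29 CPM (log2 2.78, adjusted p = 0.00221). Ripk4, Hspa1b, Rab9b, Ccl7, Inmt, Disp2, Cyp26b1 and C6 followed, with log2 changes from 2.66 to 2.02 and adjusted p from 0.000421 to 0.0167. Inmt, a methyltransferase gene, reached 231 ± 67.1 CPM from 53.9 ± 19.7, and C6, a component of terminal complement, 146 ± 49.6 CPM from 37.4 ± 14.8. The chemokine gene Ccl7 was not past the test with the duct score in the model (adjusted p = 0.152). Among genes whose groups did not overlap, without predicted genes and with a mean of at least 1 FPKM in the higher group, the deepest falls were in Adam5, a gene of the testis, from 8.08 ± 6.24 to 0.251 ± 0.209 CPM (log2 -4.90, adjusted p = 0.00357), then Art4, from 2.64 ± 1.64 to 0.228 ± 0.141 CPM (log2 -3.41, adjusted p = 0.00463). Serpinb2, Itm2a, Pdgfrl, Gprin3, Zim1, Gvin3, Adam12 and Haspin followed, with log2 changes from -2.60 to -2.25 and adjusted p from 0.000405 to 0.0103. Adam12, a metalloprotease gene, went from 122 ± 28.8 to 24.1 ± 6.90 CPM, and Itm2a from 36.5 ± 11.6 to 6.31 ± 1.64 CPM. The 5 libraries with duct RNA include 4 of the 5 WT libraries. Given the duct score, all of these genes except Ccl7 stayed past the threshold. The score does not follow germ cell RNA, which summed to 12.9 CPM in tg2 (score 4.54) and to 229 CPM in WT5 (score 2.98). With it, 4 of 5 tested germ cell markers stayed lower. A call that was kept, as for the testis gene Adam5, therefore does not exclude RNA of the genital tract. In the 1 against 4 comparison without those 5 libraries, 115 of 122 named genes lost their call, and Adam12, Itm2a and Gprin3 were among those that did not. The changes of the 115 stayed at a median of 99.6% of their log2 values in the full comparison (20.9 to 199%) while their SEs rose to a median of 171%, so most of these losses go with the small size of the comparison.

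Some of these values are uncertain because reads were counted where genes overlap or are copied. Of 132 named genes checked, 15 overlap another gene whose counts reach at least 10% of theirs: Adrb3, Cers2, Csf1r, Cxcl10, Cyp51, Dio2, Dnaja1, Fdft1, Gba2, Haspin, Ndufa2, Nrg4, Serpinb2, Srebf1 and Tlr4. Cxcl10 lies opposite Art3, with 1359 against 56192 counts over all libraries, and Adrb3 opposite Gm45470, with 128021 against 35262. Hspa1b, Hba-a2 and Gvin3 have near-identical copies elsewhere in the genome.

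The extracellular matrix list had 19 of 27 tested members lower, 1 higher and 7 not past the test, and 21 lower and 1 higher when adjusted over the list alone. Its median log2 change was -0.84 (camera adjusted p = 3.75e-09, and adjusted p = 0.727 with an estimated correlation). Col3a1 fell by 1.79 on the log2 scale (adjusted p = 0.000978). The collagen VI genes Col6a1 (748 ± 77.8 to 299 ± 32.2 CPM, adjusted p = 0.000405) and Col6a2 (594 ± 84.2 to 250 ± 32.6 CPM, adjusted p = 0.000884) fell. So did the collagen V gene Col5a1 (376 ± 61.4 to 173 ± 13.0 CPM, adjusted p = 0.000829). The cell cycle list had 17 of 26 members lower, 1 higher and 8 not past the test, and 19 lower and 1 higher when adjusted over the list alone. Its median was -1.01 (camera adjusted p = 2.77e-07, and adjusted p = 0.727 with an estimated correlation), and the call ended when only genes with a mean of 10 CPM were tested (adjusted p = 0.235). Mki67 fell by 1.70 on the log2 scale (adjusted p = 0.00178). The kinetochore gene Cenpf (8.44 ± 4.43 to 1.32 ± 0.350 CPM, adjusted p = 0.00129), the topoisomerase gene Top2a (25.0 ± 10.6 to 7.40 ± 1.57 CPM, adjusted p = 0.00257) and the mitotic kinesin gene Kif11 (9.51 to 3.31 CPM, adjusted p = 0.00316) fell. Pcna, the replication clamp gene, rose (log2 0.22, adjusted p = 0.0319) and was chosen for naming after its values were seen.

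The call of Pcna ended without any one of WT2, WT3, WT4, WT5, tg3, tg4 or tg5 (adjusted p = 0.0169 to 0.0834 over the 10 such fits), with the duct score in the model (adjusted p = 0.224) and with a correction for gene length and GC content (adjusted p = 0.0809). The duct RNA, high in WT2 to WT5 and tg2, was low in WT1, whose matrix and cell cycle genes stood at a mean of 0.54 above all libraries on the log2 scale, while tg2 stood at -0.40. In the model that includes the duct score 18 matrix and 14 cell cycle genes were lower and 0 higher (camera adjusted p = 4.35e-11 and 1.30e-08).

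**Figure D2:**
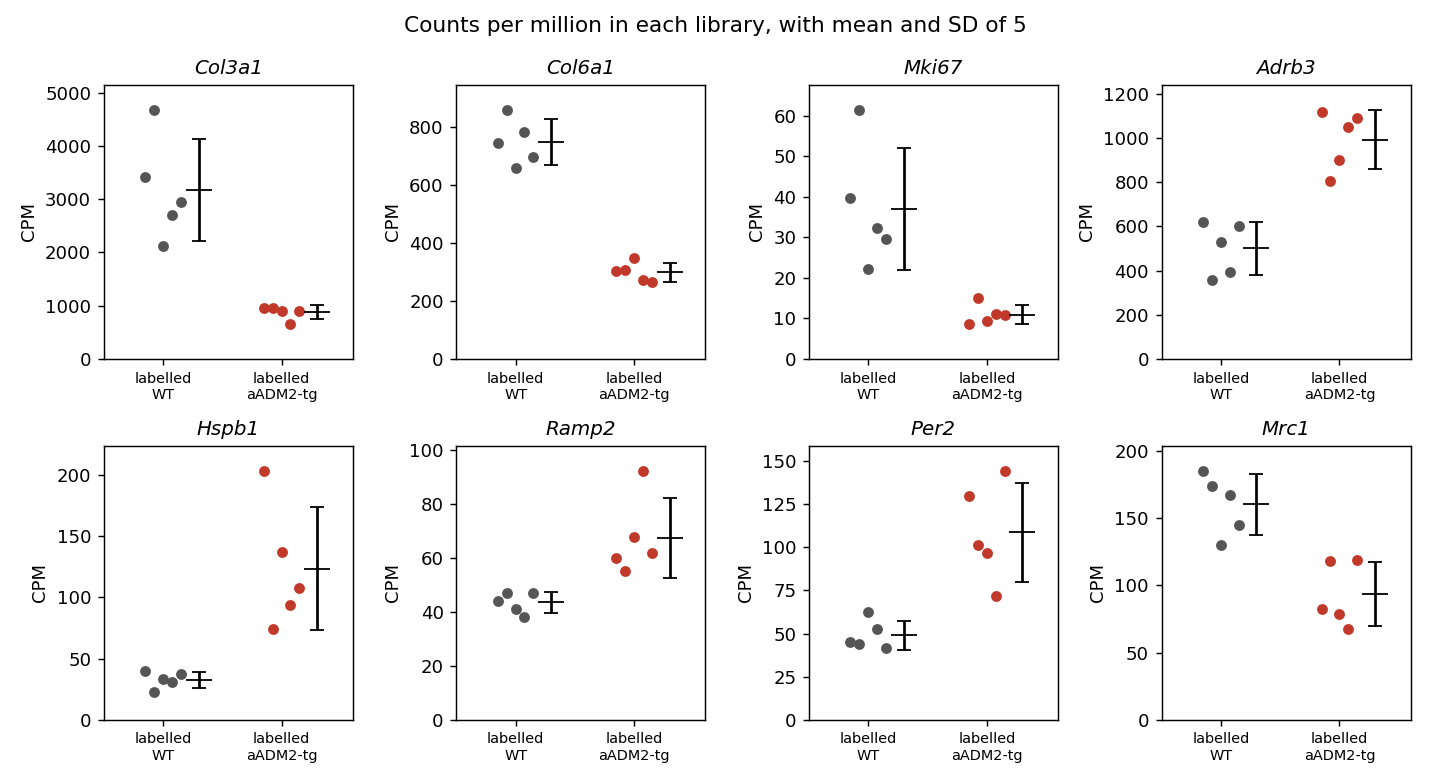
CPM in each library for 8 named genes, by group, with the mean and SD of 5 libraries. The groups do not overlap for any of the 8: Col3a1, Col6a1, Mki67 and Mrc1 are lower and Adrb3, Hspb1, Ramp2 and Per2 higher in aADM2-tg.

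Markers of adipocyte progenitors went both ways: 3 of 13 were higher, 5 lower and 5 not past the test, with the same counts when adjusted over the list alone. For progenitor markers the median log2 change was -0.45 (camera adjusted p = 0.451). Pdgfra, a receptor of fibroblasts and progenitors, fell from 101 ± 10.5 to 52.8 ± 15.5 CPM (log2 -0.88, adjusted p = 0.00372), and Cd55 from 70.9 ± 10.0 to 43.7 ± 6.50 CPM (adjusted p = 0.00976). Ly6a, which encodes the surface antigen Sca-1, rose from 111 ± 5.94 to 174 ± 22.9 CPM (log2 0.71, adjusted p = 0.00129), and F3, tissue factor, from 47.6 ± 7.58 to 93.2 ± 26.1 CPM (adjusted p = 0.00565). Adding the duct score left 2 of the list higher and 4 lower.

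The lipolysis and lipid droplet list was called higher: 11 of 18 members were higher, 0 lower and 7 not past the test, and 12 were higher when adjusted over the list alone. The median log2 change was 0.51 (camera adjusted p = 6.36e-05, and adjusted p = 0.727 with an estimated correlation). Adrb1, another beta-adrenergic receptor gene, went from 3.52 ± 0.313 to 9.27 ± 3.16 CPM (log2 1.45, adjusted p = 0.00185), and Adrb3 changed by 1.04 (adjusted p = 0.00378). The droplet coat gene Plin4 rose from 2437 ± 279 to 3751 ± 415 CPM (adjusted p = 0.00373) and the droplet fusion gene Cidec from 2010 ± 156 to 3184 ± 503 CPM (adjusted p = 0.00539). With duct RNA, high in 4 WT libraries and tg2, as a term of the model, 7 of the 18 were higher (median 0.27, camera adjusted p = 0.000899).

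Mature adipocyte markers had 8 of 18 members higher, 1 lower and 9 not past the test, and 9 higher and 1 lower when adjusted over the list alone. Over the mature adipocyte markers the median log2 change was 0.32 (camera adjusted p = 0.0383, and adjusted p = 0.727 with an estimated correlation). The droplet coat gene Plin1 rose from 1790 ± 139 to 2248 ± 172 CPM (log2 0.39, adjusted p = 0.0198) and Dgat2, an enzyme of triglyceride synthesis, from 855 ± 111 to 1278 ± 231 CPM (log2 0.65, adjusted p = 0.0152). The activin receptor gene Acvr1c fell from 421 ± 53.6 to 218 ± 35.8 CPM (log2 -0.90, adjusted p = 0.00183). The list was no longer called without WT2 (adjusted p = 0.0814), WT3 (0.0608), WT5 (0.0534), tg3 (0.0834) or tg4 (0.0585), nor with the duct score in the model (adjusted p = 0.407), where 1 member was higher and 1 lower. After correction for length and GC content 4 members were higher and 1 lower (camera adjusted p = 0.0439). The call of Plin1 ended without WT2 or WT4 (adjusted p = 0.00439 to 0.0504 over the 10 fits that each leave out 1 library), with the duct score (0.0976) and after correction for length and GC content (0.0502), and that of Dgat2 with the duct score (0.0758).

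Camera did not call the other lists of adipocyte metabolism. Among 15 adipokines and secreted factors 6 were higher, 3 lower and 6 not past the test, the same when adjusted over the list alone. For adipokines the median log2 change was 0.45 (camera adjusted p = 0.325). Nrg4 rose from 62.4 ± 11.8 to 104 ± 9.41 CPM (adjusted p = 0.00325) and Sfrp5, a secreted Wnt antagonist, from 8.87 ± 6.86 to 49.7 ± 26.3 CPM (adjusted p = 0.00938). Nampt fell from 281 ± 25.8 to 215 ± 16 CPM (adjusted p = 0.00702) and Igf1 from 437 ± 46.3 to 298 ± 45.2 CPM (adjusted p = 0.00777). Nampt (adjusted p = 0.104) and Igf1 (0.335) lost their calls after correction for length and GC content. Given the duct score, 2 adipokine genes were higher and 3 lower. For fatty acid and triglyceride synthesis 5 of 23 were higher, 2 lower and 16 not past the test, the same when adjusted over the list alone. Over the lipid synthesis genes the median log2 change was 0.12 (camera adjusted p = 0.429). The balance of calls turned with the duct score, to 2 higher and 5 lower at a median of 0.05. The lipogenic transcription factor genes Mlxipl (78.9 ± 8.69 to 123 ± 11.3 CPM, adjusted p = 0.00196) and Srebf1 (188 ± 18.0 to 261 ± 31.4 CPM, adjusted p = 0.00592) rose, and the elongase gene Elovl6 fell (78.9 ± 19.7 to 39.6 ± 10.0 CPM, adjusted p = 0.00977). Fatty acid oxidation had 2 of 23 members higher, 2 lower and 19 not past the test, the same when adjusted over the list alone. For oxidation genes the median log2 change was 0.17 (camera adjusted p = 0.255), and 0 were higher and 2 lower with the duct score (median -0.03). Its transcription factor gene Ppara fell from 8.42 ± 1.26 to 5.33 ± 0.818 CPM (adjusted p = 0.0111). The call of Ppara ended with the duct score (0.0568). Etfb, an electron transfer flavoprotein gene, rose from 57.4 ± 7.05 to 80.4 ± 14.01 CPM (adjusted p = 0.0241). The call of Etfb ended without WT2, WT3, WT4, tg3 or tg4 (adjusted p = 0.00559 to 0.0589 over the 10 fits), with the duct score (0.115) and after correction for length and GC content (0.0775).

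Insulin signalling and glucose uptake genes had 2 of 19 higher, 5 lower and 12 not past the test, the same when adjusted over the list alone. Their median log2 change was 0.10 while their mean was -0.01 and the direction of camera was lower (adjusted p = 0.650). The insulin receptor gene Insr fell from 288 ± 7.15 to 216 ± 27.3 CPM (log2 -0.35, adjusted p = 0.00823) and its substrate gene Irs1 from 46.3 ± 11.5 to 25.0 ± 4.85 CPM (log2 -0.83, adjusted p = 0.0120). The kinase gene Gsk3b fell from 126 ± 11.8 to 91.1 ± 11.9 CPM (log2 -0.40, adjusted p = 0.00546), while the kinase gene Akt2 rose from 262 ± 23.3 to 353 ± 49.3 CPM (log2 0.50, adjusted p = 0.0187). Insr was not past the test after correction for length and GC content (adjusted p = 0.359), nor Akt2 with the duct score (0.0966), nor Gsk3b with both (log2 -0.16, 0.190). With the duct score 0 of the list were higher and 5 lower, and after the length and GC correction 2 were higher and 2 lower. The thermogenic list had 0 of 13 higher, 2 lower and 11 not past the test, with 1 lower when adjusted over the list alone. Over the thermogenic genes the median log2 change was -0.46 (adjusted p = 0.164 with camera and 0.0209 with fry), and 1 was lower with the duct score. Dio2, which activates thyroid hormone, fell from 1.37 ± 0.464 to 0.322 ± 0.141 CPM (adjusted p = 0.00394). Pank1, a kinase gene of coenzyme A synthesis, fell from 12.1 ± 1.76 to 8.42 ± 1.80 CPM (adjusted p = 0.0358). The call of Pank1 ended without WT1, WT2, WT3, WT4, tg1, tg3 or tg4 (adjusted p = 0.0147 to 0.0922 over the 10 fits), with the duct score (0.148) and after correction for length and GC content (0.133).

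The nuclear-encoded respiratory chain list was called higher by camera, with 11 of 42 members higher, 0 lower and 31 not past the test, and 18 higher when adjusted over the list alone. For respiratory chain genes the median log2 change was 0.28 (camera adjusted p = 1.44e-05, adjusted p = 0.727 with an estimated correlation and 0.137 with fry). The complex I subunit genes Ndufs7 (30.5 ± 1.96 to 43.5 ± 3.41 CPM, adjusted p = 0.00205) and Ndufa2 (34.6 ± 1.43 to 52.3 ± 10.0 CPM, adjusted p = 0.00839) were among them. The list was not called with the duct score in the model (median 0.09, adjusted p = 0.0730), and 2 members were higher and 1 lower. After correction for length and GC content its median was 0.14 (adjusted p = 0.00349), and with both it was not called (adjusted p = 0.840). Of 13 mitochondrially encoded genes 1 was higher, 0 lower and 12 not past the test, and 0 were past it when adjusted over the list alone. Over the mitochondrially encoded genes the median log2 change was 0.27 (camera adjusted p = 0.0380, and adjusted p = 0.727 with an estimated correlation). The cytochrome oxidase gene mt-Co2 rose from 167 ± 20.7 to 252.1 ± 65.3 CPM (adjusted p = 0.0233). The call of mt-Co2 ended without WT3, WT4, WT5 or tg4 (adjusted p = 0.00801 to 0.0572 over the 10 fits) and with the duct score (0.129). This list lost its call without WT3 (adjusted p = 0.0887), WT4 (0.0688), WT5 (0.0545), tg1 (0.0657), tg2 (0.0703) or tg4 (0.1003) and with the duct score (0.243). Its direction turned to lower, uncalled, without the 5 libraries with duct RNA (0.688). The tricarboxylic acid cycle list had 0 of 18 higher, 1 lower and 17 not past the test, and 0 past it when adjusted over the list alone. For cycle enzymes the median log2 change was 0.04 (camera adjusted p = 0.650). With the duct score 4 of the 18 were lower and the median was -0.06 (camera adjusted p = 0.104). Pdha1, a pyruvate dehydrogenase subunit gene, fell from 507 ± 37.3 to 377 ± 34.2 CPM (adjusted p = 0.0240). The call of Pdha1 ended without tg5 (adjusted p = 0.0545).

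Ribosomal protein genes had 19 of 36 members higher, 0 lower and 17 not past the test, and 27 higher when adjusted over the list alone. Over the ribosomal protein genes the median log2 change was 0.26 (camera adjusted p = 2.10e-07, and adjusted p = 0.727 with an estimated correlation). Rplp1 rose from 167 ± 11.4 to 245 ± 38.9 CPM (adjusted p = 0.00574) and Rpl38 from 44.0 ± 3.88 to 59.6 ± 7.34 CPM (adjusted p = 0.00728). With duct RNA, high in WT2 to WT5 and tg2, in the model, 2 of the 36 were higher at a median of 0.21 (camera adjusted p = 1.25e-05), and after correction for length and GC content 6 were at a median of 0.12 (0.00385). Cholesterol synthesis had 1 of 20 members higher, 4 lower and 15 not past the test, and 2 higher and 4 lower when adjusted over the list alone. For cholesterol genes the median log2 change was -0.16 (camera adjusted p = 0.255), and 1 was higher and 3 lower with the duct score. Cyp51 fell from 54.9 ± 4.76 to 35.1 ± 6.57 CPM (adjusted p = 0.00522). The squalene synthase gene Fdft1 rose from 62.9 ± 8.02 to 83.2 ± 6.23 CPM (adjusted p = 0.00724). Glycolysis and hypoxia genes had 3 of 15 higher, 1 lower and 11 not past the test, the same when adjusted over the list alone. Over the glycolysis and hypoxia genes the median log2 change was 0.10 (camera adjusted p = 0.335), and 1 was higher and 1 lower with the duct score. The angiogenic factor gene Vegfa rose from 296 ± 24.2 to 461 ± 107 CPM (adjusted p = 0.00837) and Gpi1 from 192 ± 4.72 to 213 ± 13.6 CPM (adjusted p = 0.0152). Pdk1 fell from 63.4 ± 3.63 to 48.3 ± 5.91 CPM (adjusted p = 0.0135). Gpi1 lost its call with the duct score (adjusted p = 0.0603), where its log2 change went from 0.21 to 0.20 and its SE from 0.0518 to 0.0655, and Pdk1 after correction for length and GC content (0.0864).

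Camera did not call the lists of sphingolipid metabolism. For ceramide synthesis 3 of 13 genes were higher, 0 lower and 10 not past the test, the same when adjusted over the list alone. For ceramide synthesis genes the median log2 change was 0.11 (adjusted p = 0.167 with camera and 0.0282 with fry). The ceramide synthase gene Cers4 rose from 61.2 ± 5.69 to 73.3 ± 6.88 CPM (adjusted p = 0.0125), Kdsr from 76.6 ± 4.03 to 85.3 ± 4.21 CPM (adjusted p = 0.0308) and Cers2 from 182 ± 7.35 to 202 ± 10.5 CPM (adjusted p = 0.0396). For ceramide breakdown 1 of 9 was higher, 2 lower and 6 not past the test, the same when adjusted over the list alone. Over the ceramide breakdown genes the median log2 change was -0.09 (camera adjusted p = 0.255). The ceramidase gene Acer2 rose (log2 0.39, adjusted p = 0.0464), and Asah1 (log2 -0.22, adjusted p = 0.0245) and Acer3 (log2 -0.34, adjusted p = 0.0314) fell. The change of Acer3 turned to 0.04, uncalled, after correction for length and GC content (adjusted p = 0.734). In that fit Cers2 (log2 from 0.22 to 0.15, adjusted p = 0.0990) and B4galt6 (from -0.53 to -0.47, 0.0759) lost their calls too. Sphingomyelin and glycosphingolipid genes had 2 of 18 higher, 1 lower and 15 not past the test, and 1 higher and 0 lower when adjusted over the list alone. For sphingomyelin genes the median log2 change was 0.14 (camera adjusted p = 0.521). Sgms1, a sphingomyelin synthase gene, rose from 83.0 ± 10.0 to 110 ± 17.8 CPM (adjusted p = 0.0159). The glucosylceramidase gene Gba2 rose from 25.8 ± 3.86 to 36.4 ± 8.70 CPM (adjusted p = 0.0296), and B4galt6 fell from 30.9 ± 7.04 to 20.5 ± 5.90 CPM (adjusted p = 0.0482).

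Most of these sphingolipid calls ended when 1 library was left out, as the range of adjusted p over the 10 such fits shows. They ended for Kdsr without WT2, WT4, WT5, tg1, tg3 or tg5 (0.0199 to 0.0819) and for Cers2 without WT2 to WT5, tg1, tg3, tg4 or tg5 (0.0141 to 0.103). For Acer2 they ended without WT1 to WT5, tg1, tg3 or tg5 (0.00638 to 0.113), and for Acer3 without WT1, WT2, WT4, WT5, tg1, tg3, tg4 or tg5 (0.00379 to 0.0719). They also ended for Asah1 without WT4 or tg4 (0.0175 to 0.0579) and for Gba2 without WT1, WT2, WT3, tg1, tg4 or tg5 (0.0123 to 0.0788). For B4galt6 they ended without WT2, WT3, WT4, tg1, tg3, tg4 or tg5 (0.00446 to 0.114). With the duct score in the model Cers4, Asah1 and Sgms1 stayed past the threshold (adjusted p = 0.0367, 0.0398 and 0.0464), while Kdsr, Cers2, Acer2, Acer3, Gba2 and B4galt6 did not (0.137 to 0.294). That left 1 ceramide synthesis gene higher, 1 ceramide breakdown gene lower and 1 sphingomyelin gene higher.

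Heat shock genes rose in aADM2-tg, with 10 of 11 higher, 0 lower and 1 not past the test, and all 11 higher when adjusted over the list alone. Over the heat shock genes the median log2 change was 0.83 (camera adjusted p = 3.63e-05, and adjusted p = 0.727 with an estimated correlation). Their mean log2 CPM relative to all libraries was 0.73 to 1.15 in tg1, tg3 and tg5, 0.10 in tg2 and -0.19 in tg4. In the WT libraries it was -0.65 to -0.40, so the rise was uneven over the transgenic libraries. Hspb1 changed by 1.98 (adjusted p = 0.00159). The constitutive chaperone gene Hspa8 went from 779 ± 46.6 to 1359 ± 273 CPM (adjusted p = 0.00325). Higher too were the inducible Hspa1b, which went from 8.40 ± 1.38 to 43.8 ± 29.6 CPM (adjusted p = 0.00572) and the cochaperone gene Dnaja1 from 242 ± 11.6 to 409 ± 99.0 CPM (adjusted p = 0.00595). The unfolded protein response list had 10 of 19 higher, 0 lower and 9 not past the test, and 11 higher when adjusted over the list alone. For unfolded protein response genes the median log2 change was 0.33 (camera adjusted p = 0.00135, and adjusted p = 0.727 with an estimated correlation). Chac1 rose from 3.37 ± 0.595 to 8.97 ± 2.99 CPM (adjusted p = 0.00332) and Herpud1, a gene of endoplasmic reticulum protein degradation, from 60.1 ± 5.79 to 84.8 ± 11.8 CPM (adjusted p = 0.00441). With duct RNA in the model 6 heat shock genes (camera adjusted p = 0.000189) and 5 unfolded protein response genes (0.0199) were higher. After correction for length and GC content 10 heat shock genes (camera adjusted p = 7.16e-05) and 6 unfolded protein response genes (0.00340) were.

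Immediate early genes had 12 of 23 members higher, 1 lower and 10 not past the test, and 18 higher and 1 lower when adjusted over the list alone. Over the immediate early genes the median log2 change was 0.86 (camera adjusted p = 0.00110, and adjusted p = 0.727 with an estimated correlation). Relative to all libraries their mean log2 CPM was 1.63 in tg5 and 0.93 in tg3, and -0.39 to 0.00 in tg1, tg2 and tg4. Egr1, an early transcription factor gene, went from 25.0 ± 5.92 to 277 ± 385 CPM (log2 3.54, adjusted p = 0.0190), and its change was 2.32 without tg5 (adjusted p = 0.0384). The call of Egr1 ended with limma-trend (log2 2.08, adjusted p = 0.0869), with sample quality weights (1.99, 0.0637) and with the replicate block (2.24, 0.0811). Klf2 rose from 39.5 ± 6.29 to 77.2 ± 16.5 CPM (adjusted p = 0.00355), Klf4 from 57.7 ± 7.32 to 90.8 ± 19.3 CPM (adjusted p = 0.0101) and Jun from 73.3 ± 11.4 to 96.5 ± 13.9 CPM (adjusted p = 0.0175). Gadd45b, chosen for naming after its values were seen, fell (log2 -0.53, adjusted p = 0.0431). The call of Gadd45b ended without WT1, WT2, WT3, WT5, tg1, tg3 or tg5 (adjusted p = 0.0282 to 0.0938 over the 10 fits). Given the duct score, 3 of the list were higher and 0 lower (camera adjusted p = 0.00373), and Egr1 (0.154), Klf4 (0.0518) and Gadd45b (0.102) were not past the test. The log2 change of Gadd45b went from -0.53 to -0.55 in that fit and its SE from 0.173 to 0.208. After correction for length and GC content 6 of the list were higher and 1 lower (camera adjusted p = 0.00456), and Jun was not past the test (0.0526). Clock genes went both ways, with 5 of 18 higher, 4 lower and 9 not past the test, the same when adjusted over the list alone. Their median log2 change was 0.05, their mean -0.05 and the direction of camera higher (adjusted p = 0.751), and 3 were higher and 4 lower with the duct score. Camera tests a shift of the list in 1 direction, so it cannot detect members that move in opposite directions. The repressor genes Per2 (49.1 ± 8.47 to 109 ± 28.7 CPM, adjusted p = 0.00183) and Cry1 (9.76 ± 0.754 to 15.6 ± 2.98 CPM, adjusted p = 0.00257) rose, and the activator genes Clock (123 ± 9.03 to 63.7 ± 16.4 CPM, adjusted p = 0.00222) and Arntl (10.0 ± 1.30 to 3.88 ± 1.81 CPM, adjusted p = 0.00612) fell.

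The macrophage marker list was called lower by camera, with 0 of 17 members higher, 4 lower and 13 not past the test, the same when adjusted over the list alone. For macrophage markers the median log2 change was -0.28 (camera adjusted p = 0.0217, adjusted p = 0.727 with an estimated correlation and 0.160 with fry). Adgre1, which encodes F4/80, went from 41.6 ± 4.65 to 23.6 ± 4.29 CPM (log2 -0.77, adjusted p = 0.00299). The mannose receptor gene Mrc1 fell from 160 ± 22.5 to 93.4 ± 23.8 CPM (adjusted p = 0.00890) and the growth factor receptor gene Csf1r from 115 ± 9.40 to 74.4 ± 16.7 CPM (adjusted p = 0.0136). The call of the list ended without WT1 (adjusted p = 0.0900), tg2 (0.0789) or tg4 (0.1003), and it held with the duct score (0.00401), where 3 members were lower. Alternatively activated macrophage genes had 3 of 12 higher, 2 lower and 7 not past the test, and 4 higher and 3 lower when adjusted over the list alone. Over the alternatively activated genes the median log2 change was -0.00 (mean log2 0.06, camera direction higher, adjusted p = 0.696), and 2 were higher and 2 lower with the duct score. Il4ra rose from 33.3 ± 5.17 to 54.1 ± 12.6 CPM (adjusted p = 0.00842) and Retnla from 244 ± 17.7 to 382 ± 83.4 CPM (adjusted p = 0.00941). The lectin gene Mgl2 fell from 55.0 ± 4.90 to 36.1 ± 6.67 CPM (adjusted p = 0.0125). Lipid-associated macrophage markers had 1 of 13 higher, 1 lower and 11 not past the test, the same when adjusted over the list alone. For lipid-associated markers the median log2 change was 0.05 (camera direction lower, adjusted p = 0.910), and 1 was higher and 2 lower with the duct score. Cd63 rose (log2 0.34, adjusted p = 0.00572) and the lysosomal lipase gene Lipa fell (log2 -0.22, adjusted p = 0.0193), and both calls ended after correction for length and GC content (0.0631 and 0.745).

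Inflammatory cytokine and chemokine genes had 5 of 15 higher, 3 lower and 7 not past the test, the same when adjusted over the list alone. Over the cytokine genes the median log2 change was -0.01 (mean log2 0.39, camera direction higher, adjusted p = 0.737). Nfkbia, an inhibitor of NF-kappa-B, rose from 45.5 ± 6.07 to 88.3 ± 16.6 CPM (adjusted p = 0.00150) and the chemokine gene Cxcl1 from 1.22 ± 0.144 to 4.37 ± 2.52 CPM (adjusted p = 0.00702). The endotoxin receptor gene Tlr4 fell from 44.7 ± 1.86 to 21.6 ± 6.25 CPM (adjusted p = 0.00166). Given the duct score, 3 cytokine genes were higher and 3 lower. Antigen presentation by MHC class II had 0 of 13 genes higher, 1 lower (Cd86, log2 -0.90, adjusted p = 0.0134) and 12 not past the test, the same when adjusted over the list alone. For MHC class II genes the median log2 change was 0.13 (mean log2 -0.03, camera direction higher, adjusted p = 0.993). Of 22 interferon-stimulated genes 1 was higher, 0 lower and 21 not past the test, and 0 were past it when adjusted over the list alone. Over the interferon-stimulated genes the median log2 change was 0.13 (camera adjusted p = 0.671). That gene, Bst2 (adjusted p = 0.0493), lost its call without WT1 to WT5, tg1, tg3 or tg4 (0.0238 to 0.108 over the 10 fits), with the duct score (0.241) and after correction for length and GC content (0.266). T and NK cell markers had 2 of 14 higher, 0 lower and 12 not past the test, the same when adjusted over the list alone. For T and NK markers the median log2 change was 0.45 (camera adjusted p = 0.255). They were the T cell receptor complex genes Cd3e (0.423 ± 0.209 to 1.23 ± 0.373 CPM, adjusted p = 0.00837) and Cd3g (0.621 ± 0.1498 to 1.33 ± 0.479 CPM, adjusted p = 0.0186), of which Cd3g lost its call with the duct score (0.128). B and plasma cell markers had 1 of 14 higher, 0 lower and 13 not past the test, the same when adjusted over the list alone. Over the B cell markers the median log2 change was 0.66 (camera adjusted p = 0.335). The immunoglobulin gene Ighm rose from 204 ± 57.7 to 502 ± 223 CPM (adjusted p = 0.0113). The call of Ighm ended with the duct score (0.0944). None of 3 neutrophil and none of 6 mast cell markers was past the test over all genes or when adjusted over the list alone (mast cell median log2 -0.70, camera adjusted p = 0.0924), and the neutrophil list was too short for camera. Of these immune lists, the duct score left 1 MHC class II gene lower and 1 T and NK marker higher, and 0 past the test for the interferon-stimulated, B cell and neutrophil lists. In that fit 1 mast cell marker that was not called with genotype alone was lower. The mast cell receptor gene Kit was at 28.4 ± 5.35 and 22.5 ± 7.66 CPM and the neutrophil receptor gene Csf3r at 3.06 ± 0.549 and 2.42 ± 0.875 CPM.

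The endothelial marker list was called higher by camera, with 7 of 16 members higher, 0 lower and 9 not past the test, the same when adjusted over the list alone. For endothelial markers the median log2 change was 0.37 (camera adjusted p = 0.00310, adjusted p = 0.727 with an estimated correlation and 0.0874 with fry). The guidance receptor gene Robo4 went from 59.8 ± 8.51 to 117 ± 23.7 CPM (log2 1.03, adjusted p = 0.00194). The VEGF receptor gene Flt1 rose from 121 ± 12.0 to 223 ± 50.2 CPM (adjusted p = 0.00225) and Gpihbp1, the capillary anchor of lipoprotein lipase, from 132 ± 13.96 to 201 ± 34.3 CPM (adjusted p = 0.00575). With duct RNA in the model 5 were higher (median 0.21, camera adjusted p = 0.0316). Angiogenic growth factors had 2 of 12 higher, 2 lower and 8 not past the test, the same when adjusted over the list alone. Over the growth factor genes the median log2 change was -0.05 (camera adjusted p = 0.797). Besides Vegfa, Vegfb rose from 71.8 ± 5.77 to 102 ± 12.7 CPM (adjusted p = 0.00691), a call that ended with the duct score and the length and GC correction together (log2 from 0.57 to 0.20, adjusted p = 0.0941). Hgf, hepatocyte growth factor, fell from 9.83 ± 1.28 to 3.30 ± 1.102 CPM (adjusted p = 0.00129) and the angiopoietin gene Angpt1 from 60.2 ± 8.25 to 38.1 ± 7.98 CPM (adjusted p = 0.00996). In the same joint fit Angpt1 went from -0.60 to -0.43 and lost its call (0.110). Lymphatic endothelial markers had 0 of 7 past the test and 0 when adjusted over the list alone (median log2 -0.59, camera adjusted p = 0.281), with Lyve1 at 55.5 ± 9.42 and 44.8 ± 15.2 CPM. Pericyte and smooth muscle markers had 1 of 14 higher, 0 lower and 13 not past the test, and 0 past it when adjusted over the list alone. Over the pericyte markers the median log2 change was -0.03 (camera adjusted p = 0.737). Mylk, the myosin light chain kinase gene, rose from 165 ± 17.8 to 205 ± 39.2 CPM (adjusted p = 0.0254). The call of Mylk ended without WT1, WT4, WT5 or tg1 (adjusted p = 0.0106 to 0.0662 over the 10 fits). Mesothelial markers had 0 of 15 past the test and 0 when adjusted over the list alone (median log2 -0.41, camera adjusted p = 0.180), with Upk3b at 71.7 ± 23.9 and 59.5 ± 44.2 CPM. Nerve and Schwann cell markers had 0 of 6 higher, 2 lower and 4 not past the test, the same when adjusted over the list alone. Over the nerve markers the median log2 change was -0.73 (adjusted p = 0.0818 with camera and 0.0319 with fry). The duct score left 2 nerve markers lower and camera then called the list at the preset correlation (adjusted p = 0.0316), while with genotype alone it was at 0.727 with an estimated correlation. The neurotrophin receptor gene Ngfr fell from 1.15 ± 0.475 to 0.274 ± 0.201 CPM (adjusted p = 0.00949). For angiogenic factors 2 were higher and 2 lower in that fit, for pericyte markers 1 was higher and 1 lower, and for lymphatic and mesothelial markers 0 were past the test.

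Male germ cell markers were lower in aADM2-tg in 5 of 5 tested genes, also when adjusted over the list alone. For germ cell markers the median log2 change was -5.08 (camera adjusted p = 0.0168, and adjusted p = 0.727 with an estimated correlation). The protamine gene Prm2 was at 27.2 ± 26.8 and 0.743 ± 1.596 CPM (adjusted p = 0.0240). The sperm sheath gene Akap4 was at 13.1 ± 11.3 and 0.292 ± 0.621 CPM (adjusted p = 0.0217) and the testis kinase gene Pgk2 at 7.80 ± 6.61 and 0.219 ± 0.426 CPM (adjusted p = 0.0193). The duct score left 4 germ cell markers lower (median -3.91, camera adjusted p = 0.0286). Without tg2, which carried germ cell RNA, their log2 changes went from -5.16 to -9.45, from -5.42 to -9.13 and from -5.08 to -7.64. In the other transgenic libraries these genes lay at 0 to 0.119 CPM, under the limit of 3 counts. The sizes of these larger changes thus come from the fit and were not measured. The change of Prm2 was -4.56 without WT5, and its call ended without WT2, WT5, tg1, tg3 or tg4 (adjusted p = 0.00365 to 0.0694 over the 10 fits) and that of Akap4 without tg3 (0.0507). With sample quality weights Adam5, Prm2, Akap4 and Pgk2 were not past the test (adjusted p = 0.0880, 0.227, 0.195 and 0.108). Of 2 tested epididymal genes 0 were past the test, over all genes or when adjusted over the list alone. Gpx5 was at 137 CPM in WT3, at 148 CPM in tg5 and at 0 to 4.49 CPM in the other 8 libraries.

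Liver markers had 1 of 10 members higher, 0 lower and 9 not past the test, and 0 past it when adjusted over the list alone. Over the liver markers the median log2 change was 1.01 (camera adjusted p = 0.0296, and adjusted p = 0.727 with an estimated correlation). Their mean log2 CPM relative to all libraries was 1.42 in tg4 and -0.68 to 0.19 elsewhere. The transferrin gene Trf, which fat also expresses, rose from 3053 ± 339 to 4120 ± 731 CPM (adjusted p = 0.0346). The call of Trf ended without WT2, WT3, WT4, tg1, tg3 or tg4 (0.00781 to 0.0834 over the 10 fits), with the duct score (0.228) and after correction for length and GC content (0.0642). The list lost its call without WT3 (adjusted p = 0.0600) or tg4 (0.0503), with the duct score (0.0960) and after correction for length and GC content (0.0850). Erythroid markers had 1 of 6 higher, 0 lower and 5 not past the test, and 4 higher when adjusted over the list alone. For erythroid markers the median log2 change was 0.99 (camera adjusted p = 0.0478, and adjusted p = 0.727 with an estimated correlation). The globin gene Hba-a2 rose from 8.93 ± 4.60 to 19.7 ± 7.84 CPM (adjusted p = 0.0247). The call of Hba-a2 ended without WT1, WT3, WT4, WT5 or tg3 (0.00945 to 0.0629 over the 10 fits) and after correction for length and GC content (0.0678). The erythroid list lost its call without WT1 (0.0756), WT3 (0.0773), WT4 (0.0657), WT5 (0.0696), tg2 (0.135), tg3 (0.0714), tg4 (0.0503) or tg5 (0.0887) and after correction for length and GC content (0.104). It held with the duct score (camera adjusted p = 0.00443), with 5 members higher. Of 5 skeletal muscle markers and 1 pancreatic acinar marker 0 were past the test, over all genes or when adjusted over the list alone (skeletal muscle median log2 -0.09, camera adjusted p = 0.751). The muscle myosin gene Myl1 was at 52.4 ± 7.58 and 46.9 ± 6.92 CPM and the elastase gene Cela1 at 7.63 ± 1.99 and 8.27 ± 1.61 CPM. Of 4 sex-linked genes 2 were lower and 2 not past the test, and 3 were lower when adjusted over the list alone. The Y-linked genes Ddx3y (173 ± 26.5 to 90.0 ± 14.5 CPM, adjusted p = 0.00120) and Uty (44.95 ± 7.86 to 23.8 ± 4.69 CPM, adjusted p = 0.00260) fell in these male mice, and the call of Uty ended with the duct score and the length and GC correction together (log2 from -0.85 to -0.41, adjusted p = 0.0583). The duct score left 2 sex-linked genes lower, 0 liver markers past the test and 0 of the epididymal and acinar genes. In that fit 1 skeletal muscle marker that was not called with genotype alone was lower.

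Of 43 lists long enough for camera, 11 were higher and 4 lower, and 0 of these 15 calls held with an estimated correlation, where 0 of the 43 lists had an unadjusted p under 0.05. With limma's fry, which tests each list against no change, 5 of the 15 were past the threshold. Of the same 15 lists, 11 were called in the same direction with the duct score in the model and 13 after correction for length and GC content. Of the named genes, 24 lost their call with the duct score, with log2 changes at 50.7 to 104% of those without it (median 69.8%) and SEs at a median of 109%. With the length and GC correction as well 42 lost it while keeping their direction, at 23.7 to 108% (median 58.2%). Acer3, not among them, lost its call and changed direction. Of the 42, 15 were called with either alone: Angpt1, Asah1, Cd86, Creld2 (of the unfolded protein response list), Fdft1, Gsk3b, Herpud1, Hspa1b, Ndufa2, Ramp2, Retnla, Rpl38, Rplp1, Uty and Vegfb.

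**Figure D3:**
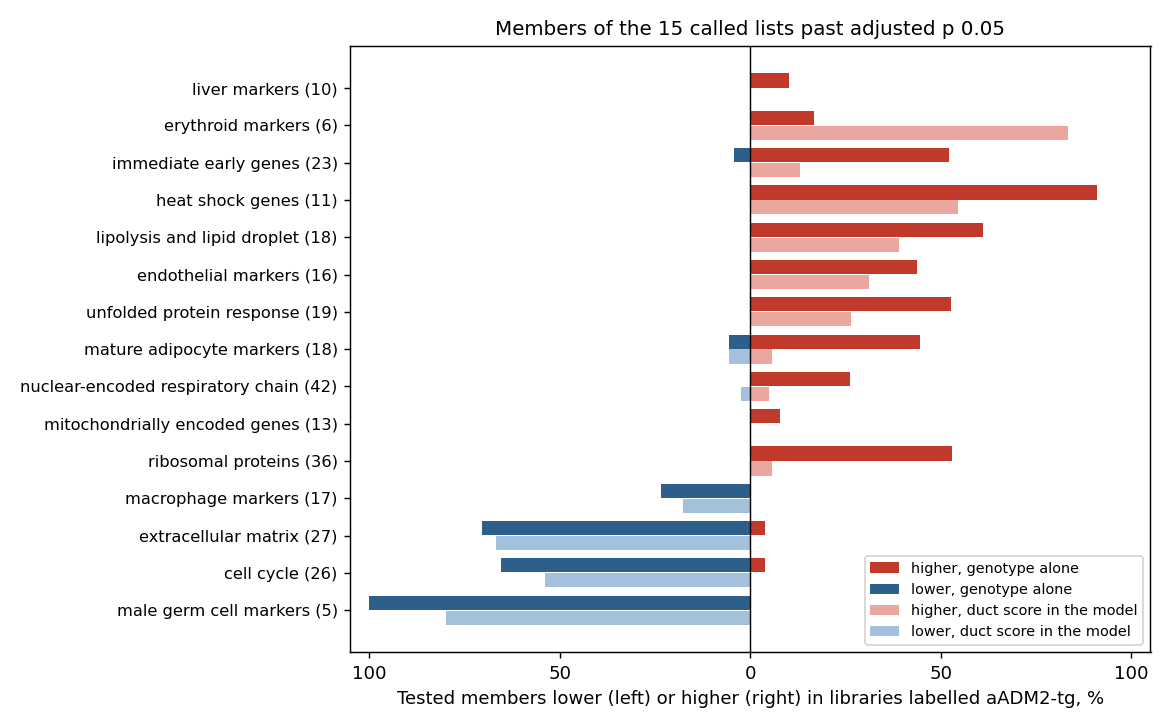
Percent of tested members past an adjusted p of 0.05 in each of the 15 called lists, lower to the left and higher to the right, for the fit with genotype alone and for the fit with the duct score added. Extracellular matrix and cell cycle genes stay lower in both (19 and 18 of 27, 17 and 14 of 26). The ribosomal protein list goes from 19 to 2 of 36 members higher, while its median log2 change goes from 0.26 to 0.21 and the list stays called (camera adjusted p = 1.25e-05).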

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

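The tests of the header labels, of genital tract tissue, of exchanged libraries, of duct RNA and of progenitors below were chosen only after the result was seen, and so was the correction for length and GC content, although its threshold was set before its result.

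In 33 of 276 sets of 5 values, 1 library lay far from the other 4 of its group, where chance gives about 5%, or 1 in 20. Of these, 11 were in tg2, 6 in tg5, 4 each in WT1, WT2 and WT3, 2 in WT4 and 1 each in WT5 and tg4. WT1 lay at -39.3 on the first principal component (others 43.4 to 72.6) and at -1.64 on the duct score (others 2.98 to 4.16). In tg2 the same measures were 62.0 (others -71.6 to -57.7) and 4.54 (others -1.84 to -1.19), and its summed germ cell CPM was 12.9 (others 0.250 to 0.720). Germ cell genes stood out in tg2 one by one, with Akap4 at 1.40 CPM (others 0 to 0.0596), Pgk2 at 0.976 CPM (others 0 to 0.119) and Prm2 at 3.60 CPM (others 0 to 0.119). Also in tg2, Ramp1 was at 5.91 CPM (others 1.31 to 2.44), Ramp3 at 5.12 CPM (others 0 to 0.655), Plin1 at 1953 CPM (others 2276 to 2401), Gpi1 at 237 CPM (others 203 to 208) and B4galt6 at 30.7 CPM (others 15.5 to 19.4).

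Epididymal genes summed to 263 CPM in WT3 (others 2.03 to 18.6) and to 325 CPM in tg5 (others 0.360 to 12.1). Their genes Gpx5 and Adam7 were at 137 and 45.1 CPM in WT3 (others 0 to 4.49 and 1.05 to 6.91) and at 148 and 52.6 CPM in tg5 (others 0 to 0.437 and 0 to 10.9). In tg5 Cyp1a1 was at 16.2 CPM (others 5.98 to 7.26), Flt1 at 310 CPM (others 184 to 220) and Il4ra at 76.0 CPM (others 45.1 to 51.8), and in tg4 Col3a1 was at 659.5 CPM (others 903.5 to 967.3). In WT1 Elovl6 was at 113 CPM (others 65.4 to 78.9) and Serpinb2 at 5.09 CPM (others 2.201 to 2.93). In WT2 Adrb1 was at 2.98 CPM (others 3.60 to 3.78), Cenpf at 16.03 CPM (others 4.52 to 7.64), Hba-a2 at 17.1 CPM (others 6.12 to 7.68) and Pdgfrl at 12.5 CPM (others 4.21 to 6.49). In WT3 Hspa1b was at 10.8 CPM (others 7.37 to 8.26), in WT4 Nfkbia at 56.1 CPM (others 40.9 to 44.8) and Sfrp5 at 20.8 CPM (others 3.32 to 7.27), and in WT5 Srebf1 at 156 CPM (others 190 to 201).

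The 2 header lines of the file name the groups in opposite ways. If the groups carried each other's labels, transgenic Adm2 reads would be expected in the columns labelled WT, and if not, in those labelled aADM2-tg. The highest Adm2 count in any library was 2, under the limit of 3 counts, so the explanations cannot be told apart from this gene, and each direction reported here would turn if the first header line were the right one. No other value in the tables decides it, and no biological explanation applies to a header.

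RNA of duct epithelium and germ cells was high in WT2, WT3, WT4, WT5 and tg2. Tissue of the male genital tract in the sampled fat is a candidate explanation: 80% of the 10 germ cell genes, a list fixed in advance, were higher in each of the 5 libraries than in each of the other 5, where chance gives 0.397%, and the duct gene Lrp2 was at 53.7 to 129.3 CPM against 1.59 to 10.6. The evidence is weak, since the threshold was set with the values per library known, an earlier form of it, that germ cell genes stand above 3 counts in those 5 libraries only, would not have been met (40 counts in WT1 and 12 in tg1), and the 27 duct genes, of which 25 separate the libraries and 3 average at least 1 CPM in the 5 without duct RNA, were chosen on the pattern. Whether WT1 and tg2 were exchanged could not be settled. WT1 lay above tg2 by 0.94 on the mean log2 CPM of the matrix and cell cycle genes, with every WT library above every transgenic one. These lists were picked because they differed between the labelled groups, so this cannot exclude an exchange. The first principal component, the duct score and the closest library set WT1 with transgenic libraries and tg2 with WT ones. RNA of the 27 duct genes and of germ cells was high in 4 of 5 WT and 1 of 5 transgenic libraries. Epididymal genes summed to 263 CPM in WT3 and 325 CPM in tg5, although the duct score of tg5 was low (-1.19). The duct score thus misses this RNA in tg5, and tg5 stays in the fit without the 5 libraries. The germ cell list was called lower in aADM2-tg and none of the 27 duct genes was. Whether genotype caused the difference in such RNA was not tested.

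Extracellular matrix and cell cycle genes were lower in aADM2-tg, with 36 called lower (median log2 -1.20, SD 0.438). With the duct score in the model 88.89% of the 36 were still called lower (median -1.22, SD 0.416). That fit rests mainly on WT1 and tg2, the libraries that part from their group on the duct score, and the 36 were picked in these data. It therefore argues only weakly against duct RNA as the whole cause. A trend with gene length and GC content as the whole cause was argued against for these same 36 genes, again picked in these data. Of them 97.22% were still called after its correction (median -1.27, SD 0.404). A loss of adipocyte progenitors cannot be told apart from a change within cells. If it were the cause, their markers would fall alike and by about as much, and if not, their median would lie above that of the 36 genes by more than the SD of the markers in each of 4 fits. It lay above by 0.7457 with genotype alone, under the SD of 0.749, and by 1.02 to 1.23 in the fits with the duct score, the length and GC correction or both (SD 0.702 to 0.732). Some markers were called higher, 3 with genotype alone and 2 in each other fit, against 5 and 3 or 4 lower. This is not the common fall that a loss predicts, but a part of other cells in these markers was not tested. A loss also stays open because of the fit with genotype alone, where the gap does not exceed the spread of the markers. An earlier form of this test, which asked for 3 markers called higher, was set with that count known and is not used. Without the 5 libraries with duct RNA, with 1 WT library left, 8 of the 36 were still called, Col3a1, Col5a1, Mki67 and Top2a among them, the median was -1.40 (SD 0.485), and camera at the preset correlation called both lists lower (adjusted p = 6.39e-11 and 2.39e-12). Over all libraries neither list was called with an estimated correlation (adjusted p = 0.727), and 1 WT library is too few to weigh the pattern. An effect of the transgene on matrix genes and on proliferation was not tested and stays open, as do other differences between the groups of mice and the opposite direction should the labels be exchanged. Matrix transcripts and dividing cells could be counted in sorted progenitors, from mice with measured transgene RNA and fat free of genital tract tissue. There an effect within progenitors predicts lower matrix transcripts per cell, and a loss of progenitors predicts fewer such cells with unchanged transcripts. Such counts would separate these 2 only, since the cells that hold the 36 changed genes were not identified here.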

How the results depend on the processing

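The added fits (duct score, length and GC correction, both together, and the fits without WT1 and tg2 or without the 5 libraries with duct RNA) were chosen after seeing the data, and the others were planned. No called gene changed sign while called in any of the planned fits, and 4 did after the length and GC correction. The gene counts stayed within 1.5 times of 2285 higher and 2107 lower with DESeq2 size factors (2249 and 2131), DESeq2 (2632 and 3068), limma-trend (1716 and 2027), voom with sample quality weights (3013 and 2809), no expression filter (1854 and 2305), a filter at 10 CPM (1744 and 1847), the replicate block (1853 and 2114) and the length and GC correction (2149 and 1607). With the duct score in the model 822 genes were higher and 1310 lower, and with the length and GC correction as well 974 and 913. Without the 5 libraries with duct RNA 1 was higher and 34 lower, in a comparison of 1 library against 4 whose small size limits it. Without WT1 and tg2 3622 were lower, but there every WT library has a high duct score and no transgenic one has. Without tg2 no transgenic library with a high duct score is left either. Larger counts in these fits cannot be read as a stronger effect of genotype. Leaving out each library in turn gave 1370 to 3050 higher and 1609 to 3629 lower genes, lowest without WT2 and highest without tg2, and counts of higher genes more than 1.5 times below 2285 also came without WT3 (1505), WT4 (1518) and WT5 (1515).

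The count of higher lists, 11 as reported, was 7 with limma-trend, 7 with the filter at 10 CPM, 4 with fry, 7 with the duct score, 7 with that score and the length and GC correction, and 5 without the 5 libraries with duct RNA. The count of lower lists, 4 as reported, was 2 with the filter at 10 CPM, which tests 9760 genes in place of 16591, and 7 with the replicate block. With an estimated correlation 0 lists were higher and 0 lower, and the lowest unadjusted p was 0.0619. Leaving out each library in turn gave 7 to 10 higher lists, 7 without WT3 and without tg4, and 3 to 5 lower lists. For the other changes of count the cause was not tested.

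Of 125 named genes with a call, 0 lost it with DESeq2, 11 of 108 with limma-trend, 5 with voom, 12 with no filter, 1 of 94 with the filter at 10 CPM, 8 with the replicate block, 24 with the duct score, 16 with the length and GC correction, 42 with both, and up to 16 when 1 library was left out. Acer3 alone reversed, to 0.039 after the length and GC correction (adjusted p = 0.734) and to 0.024 with the duct score as well (adjusted p = 0.904), and the cause was not tested. Its call ended in these 2 fits too, but it is not among the 16 and the 42, which kept their direction. Losses with limma-trend were in Acer2, Acer3, Bst2, Cers2, Cers4, Egr1, Gba2, Gpi1, Kdsr, Mylk and Pank1, and with voom in Adam5, Akap4, Egr1, Pgk2 and Prm2. With no filter they were in Acer3, Asah1, B4galt6, Bst2, Cers2, Gadd45b, Lipa, Pank1, Pcna, Pdha1, Plin1 and Trf, and with the replicate block in Acer2, Acer3, Asah1, Bst2, Egr1, Gadd45b, Pcna and mt-Co2. The numbers of tg3 to tg5, on which that block rests, differ between the labels. No pairing common to all the numbers used was seen: over the 5 numbers, deviations from the group means correlated across genes at -0.385 to 0.674, above 0.1 for 2, and 2 of 5 libraries were closest to the one of their own number. The Adm2 difference in log2 of CPM plus 1 was -0.03 and stayed between -0.04 and 0 when 1 library was left out, all under the limit of 3 counts, so depth limits any statement on Adm2. The alternatives planned for a file with FPKM alone (a pseudocount of 0.1, median-ratio scaling and counts recovered from FPKM) were not run, since counts were at hand.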

Other observations

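The gene ontology terms, the trends with length and GC content, and the duct score behind them were examined only after the data were seen, while the splits of the libraries were planned.

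Beyond the fixed lists, gene ontology terms of RNA processing and protein making were called higher by camera. Of 2111 terms tested with camera 34 were higher and 33 lower, and 8 and 5 of these were also called with the duct score and after the length and GC correction. The rRNA processing term had 55 of 136 genes higher and 2 lower (adjusted p = 1.76e-07), complex I assembly 24 of 66 higher and 0 lower (2.21e-06), spliceosomal mRNA splicing 71 of 186 higher and 8 lower (7.40e-05), mitochondrial translation 14 of 41 higher and 0 lower (0.000119) and protein folding 32 of 100 higher and 5 lower (0.00206). Among lower terms, collagen fibril organization had 22 of 41 genes lower and 2 higher (0.000208), mitotic cytokinesis 26 of 53 lower and 4 higher (0.00206) and homophilic cell adhesion 23 of 117 lower and 6 higher (0.00299). The wider terms translation (76 of 288 genes higher and 6 lower, 4.61e-07) and cytoplasmic translation (44 of 154 higher and 3 lower, 2.11e-06) lost their calls after the length and GC correction (0.0658 and 0.188). None of these terms held with an estimated correlation (adjusted p = 0.888).

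Changes ran with gene length and GC content. Across genes, which are not independent replicates, log2 change had a Spearman correlation of -0.29 with exonic length and 0.23 with GC content. With the genes in 5 bins by exonic length, 608 in the shortest bin were higher and 117 lower (median log2 0.19), and 215 in the longest bin were higher and 990 lower (median -0.19). Within libraries the correlation of expression relative to all libraries with length was 0.144 to 0.270 in the WT libraries, 0.022 in tg2 and -0.293 to -0.091 in the other transgenic libraries.

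Chance splits of the libraries were compared with the real one. The real split gave 4392 called genes, and 1 of 100 splits, the real one, gave as many. The real split was always among the 100 drawn of 126, so this is the lowest share possible. Chance is thus unlikely for that count but cannot be excluded. The highest other split gave 3856 genes and set WT1, tg1, tg3, tg4 and tg5 against the libraries with duct RNA, which points to a structure of the samples. A count of this size does not by itself point to genotype. For lists the real split gave 15 calls, 30 of 100 splits gave as many, and the highest other gave 21, so chance cannot be excluded for the number of called lists.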
